A study of Mus musculus with 8 samples.

How the data were processed

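Total RNA of Stat3 WT and Stat3 KO mouse embryonic fibroblasts, untreated or treated with OSM, was labelled with biotin and hybridised to Affymetrix arrays by the authors, per the labels' protocols. The medium held 10% serum and 2 mM glutamine. The deposited values are log2 expression values per probe set, made with GCRMA and the affy package per the submitters' processing notes. The versions of these tools, and whether all arrays were normalized together, are not given in the sources used here. GCRMA pulls dim probe sets to low values that differ little between arrays, which can enlarge the log2 difference of a transcript that is dim in 1 group. Scanner files were not used here. The table held 12488 probe sets, of which 66 controls were set aside. In the platform annotation 10833 probe sets have 1 gene symbol, 396 have several and 1193 have none. Gene IDs of 10817 single-symbol probe sets matched the RefSeq gene table of assembly GRCm38.p6, which was used for names only. Probe sets with several symbols were tested but not named.

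Groups and replicate numbers come from the sample titles. Nothing in the labels says whether the arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. No arrays of a group were near-identical. Differences were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend on all 8 arrays with 4 group means and 4 residual degrees of freedom, two-sided. Probe sets were kept where the log2 value was at least 5 on at least 2 arrays. Benjamini-Hochberg adjustment ran over the 6756 probe sets kept, and an adjusted p under 0.05 was called. A gene was represented by the kept probe set with the highest mean. Errors of log2 differences are limma standard errors. The 5 comparisons, the filter, the gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined, and all others are named as chosen later.

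Replicate numbers were checked for pairing before the fits were compared. The differences between replicate 3 and replicate 2 correlated at 0.9106 between the Stat3 WT groups and 0.7935 between the Stat3 KO groups. Between groups of different genotype they correlated at 0.589 to 0.6638. The number was therefore treated as pairing the samples on the evidence of the data. The block fits 1 difference for all groups, so it does not remove a difference that is unequal between the genotypes. The labels do not say what the number marks. The planned fit has no block. The replicate block leaves 3 residual degrees of freedom, and it reduced the median standard error from 0.49 to 0.28 (0.69 to 0.40 for the interaction).

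Gene lists were tested with limma's camera at a preset correlation of 0.01, against all other genes, with adjustment over the 20 lists with at least 5 tested members. The lists were immediate early genes, STAT3 targets, gp130 JAK-STAT components, MAPK feedback genes, interferon-stimulated genes, NF-kB and chemokine genes, fibroblast matrix, contractile genes, matrix proteases, proliferation, p53 and CDK inhibitors, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, heat shock, antioxidant and HOX genes, and markers of muscle, endothelium and adipocytes. A further 5 lists had too few tested members and are given as values, namely markers of epithelium, leukocytes, neural cells, and cartilage and bone, and sex-linked genes. Of 712 list memberships 582 were on the array, 7 of them through a synonym. Members were also adjusted over the list alone. Some genes belong to more than 1 list. Stat3 itself is a member of the STAT3 target and gp130 lists, so its own level enters them in the genotype comparisons.

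Genes were named by a fixed rule. It takes Stat3 on every array, and up to 10 genes up and 10 down per comparison that pass without overlap between the groups. Where none pass it takes the 5 genes with the smallest p, named as not passing. It adds up to 4 passing members per list, passing members of the immediate early, STAT3 target and MAPK feedback lists for the OSM comparisons, and Socs3, Fos, Egr1, Junb, Bcl3, Cebpd, Myc, Osmr, Il6st, Lifr and Il6 whatever their result. An item of the rule is not reported here. Members that pass only when adjusted over their list alone are named as such, and these and the genes called with the replicate block lie outside the rule and were chosen after their values were seen.

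The other settings were no filter, a stricter filter at log2 7, eBayes without the trend or with robust estimation, only the groups compared, renewed quantile normalization, median centring, the replicate block, an added 2-fold threshold, 1 probe set per gene, a rule of 2-fold separation without a test, other probe sets of a gene, and leaving out each array. For the lists they were camera with an estimated correlation and limma's fry. After the data were seen, values under 5 set to 5, list tests leaving out each array, and the replicate block without Stat3 KO OSM replicate 3 were added. Where an array is left out, the lone array of its group is assumed to vary like the other groups.

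The fits were tested on simulated data for OSM in Stat3 WT cells, with 6756 probe sets, 50 of them changed by each of the sizes below. With differences between replicate numbers as large as in the data, the fit without a block recovered 0% of log2 changes of 1, 14% of 2, 66% of 4 and 74% of 6, with 0 false calls. The replicate block recovered 22%, 52%, 96% and 90%, with 10 false calls. The simulated difference between numbers was the same in all 4 groups, as the block assumes, and the noise was independent. In the data that difference was unequal between the genotypes, so these rates need not hold for the genotype comparisons or the interaction. In data simulated without a difference between numbers, a list of independent genes shifted by 1 was called by camera, with 0 of the other lists called. This does not show how camera behaves for correlated genes. The estimated correlation was 0.87 for the interferon-stimulated genes and 0.76 for the proliferation genes.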

Results

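Transcript levels were measured in mouse embryonic fibroblasts, connective tissue cells grown from embryos, with and without the transcription factor Stat3. Each line had immortalised spontaneously in culture. One line carried both copies of Stat3 (Stat3 WT) and the other carried neither (Stat3 KO). As 1 line stands for each genotype, effects of Stat3 cannot be told apart from other differences between the lines. This holds for each genotype comparison and for the interaction. Cells of each line were left untreated or given oncostatin M (OSM), a cytokine of the interleukin-6 family that signals through gp130 receptors to the JAK kinases, Stat3 and the MAP kinases, at 20 ng/ml for 30 minutes. The 4 groups held 2 arrays each, replicates 2 and 3, and these 8 arrays limit the precision of every value. The sample titles assign the treatment, because the growth text mentions OSM for untreated samples too. Values are log2 GCRMA expression values per probe set, from -1.16 to 17.18, with array medians from 5.27 to 5.66. On each array 51.1% to 52.9% of the probe sets reached the log2 floor of 5 used for filtering, and 6756 probe sets of 5195 genes were tested.

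Stat3 itself was lower in the Stat3 KO arrays. The Stat3 probe set with the highest mean read 10.11 and 10.50 in replicates 2 and 3 of untreated Stat3 WT cells, 11.82 and 11.94 with OSM, 8.08 and 7.81 in untreated Stat3 KO cells, and 8.70 and 9.17 with OSM. Its mean was 10.31 ± 0.28 (SD, n = 2) without OSM in Stat3 WT and 7.94 ± 0.19 (SD, n = 2) in Stat3 KO cells. With OSM the means were 11.88 ± 0.08 and 8.94 ± 0.33 (SD, n = 2 each). The other Stat3 probe set read 9.80 and 10.95 in untreated Stat3 WT cells, 2.76 and 2.86 in untreated Stat3 KO cells, and 11.99 and 12.57 in Stat3 WT cells with OSM. In Stat3 KO cells with OSM it read 2.94 in replicate 2 but 7.30 in replicate 3, which stands apart from the other 3 Stat3 KO arrays. Where the deleted part of Stat3 lies relative to these probes is not given in the sources used here, so the remaining signal of the first does not check the labels.

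Arrays with the same replicate number resembled each other more than arrays of the same group. Correlations across probe sets were 0.9325 to 0.977 between arrays of one number and different groups, against 0.8694 to 0.9258 between both arrays of a group. The first principal component separated the numbers and held 56% of the variance, although Stat3 KO OSM replicate 2 lay at -19.43 and the other replicate 2 arrays at -54.69 to -48.05. That array had a correlation of 0.9303 with Stat3 KO untreated replicate 3, above each correlation within a group, and it enters the OSM effect in Stat3 KO, the interaction and the genotype effect with OSM. With number as a term in limma, 2775 probe sets (41.1%) differed between replicates, 1582 of them higher in replicate 3. The interferon-stimulated genes were higher in replicate 3, with a median difference of 3.41 and 31 of 31 members above 0 (camera adjusted p = 7.37e-10, and adjusted p = 0.541 with an estimated correlation). The proliferation genes were lower there, with a median of -2.19 (camera adjusted p = 5.34e-09, and adjusted p = 0.568 with an estimated correlation). The 18S 3' control read 11.02 to 11.67 in replicate 2 and 14.75 to 15.13 in replicate 3. Of the 9 spiked control probe sets 7 were lower in replicate 3 without overlap, the BioB 3' control reading 9.78 to 10.05 and 6.73 to 7.36, while the CreX 3' control overlapped at 14.87 to 14.96 and 14.66 to 14.94. The 3' minus 5' difference of the actin control, a sign of RNA quality, was 0.33 to 0.53 in replicate 2 and 0.72 to 1.11 in replicate 3, while that of Gapdh overlapped at 0.03 to 0.11 and 0 to 0.27. Each replicate number held all 4 groups, so values within each number or with number as a block are given beside many results. Leaving out 1 array ends that balance, and by construction adds part of the difference between numbers to the comparison. A call lost or turned below in such a fit without a block therefore does not by itself show that it rests on that array. Log2 values under 5 were read as near background, so differences from them are not exact.

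The first comparison asked how the Stat3 KO line differed from the Stat3 WT line before any cytokine was added. Cx3cl1, a membrane-bound chemokine, read 13.10 ± 0.49 in Stat3 KO and 7.91 ± 0.02 in Stat3 WT cells (SD, n = 2 each), a log2 difference of 5.19 ± 0.50 (SE). Psmb8, an immunoproteasome subunit, differed by 5.51 ± 0.95, and the matrix proteins Postn and Tnc by 4.02 ± 0.49 and 2.17 ± 0.39 (SE). Stat3 differed by -2.36 ± 0.33 (SE). These 5 genes had the smallest p-values and none passed the test over all probe sets. Their limma adjusted p-values were 0.288 for Cx3cl1, 0.564 for Postn, 0.739 for Stat3 and 1 for Psmb8 and Tnc.

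Among the fixed gene lists, the interferon-stimulated genes were higher in untreated Stat3 KO cells, with a median log2 difference of 1.68 and 30 of 31 members above 0 (camera adjusted p = 4.64e-06, and adjusted p = 0.913 with an estimated correlation). Within replicate 2 the median was 0.13 and within replicate 3 it was 2.30. The call did not hold without Stat3 WT untreated replicate 2, and without Stat3 KO untreated replicate 3 the median was -0.55. Both fits are unbalanced in replicate number, which by itself shifts the median of these genes. The contractile genes were higher, with a median of 0.36 and 10 of 12 above 0 (camera adjusted p = 0.00424, and adjusted p = 0.913 with an estimated correlation), but not without Stat3 WT untreated replicate 3 (adjusted p = 0.346) or Stat3 KO untreated replicate 3 (adjusted p = 0.305). The fibroblast matrix genes also passed camera (adjusted p = 0.00424, and adjusted p = 0.913 with an estimated correlation), with a median of only 0.08. Within replicate 2 their median was 0.34 with 25 of 30 members above 0, and within replicate 3 it was -0.10 with 10 above 0, and the call was lost without Stat3 WT untreated replicate 2 (adjusted p = 0.561). The matrix proteases had a median of 0.14 (camera adjusted p = 0.0413, and adjusted p = 0.913 with an estimated correlation), and leaving out Stat3 WT untreated replicate 2, Stat3 KO untreated replicate 2 or Stat3 KO untreated replicate 3 ended that call (adjusted p = 0.465, 0.083 and 0.209). Within replicates 2 and 3 the contractile medians were 0.08 and 0.55 and the protease medians 0.62 and 0.16. The matrix and protease calls were also lost with the most variable probe set per gene (adjusted p = 0.138 each), and the protease call after quantile normalization (adjusted p = 0.0807) and with values under 5 set to 5 (adjusted p = 0.0556). The other 16 lists did not pass, with camera adjusted p-values from 0.052 to 0.934. Among them the proliferation genes went in opposite directions within the numbers, which the pooled median of 0.16 hides. Within replicate 2 their median was -0.78 with 4 of 32 above 0, and within replicate 3 it was 1.01 with 31 above 0.

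Adjusted over the list alone, 1 interferon-stimulated gene (Psmb8), 2 matrix genes (Postn and Tnc), 1 protease (the gelatinase Mmp9, 3.64 ± 0.71, SE), 2 NF-kB and chemokine genes (Ccl5, 3.29 ± 0.64, SE, and Cx3cl1) and Stat3 passed. The replicate block added the STAT3 target gene Cebpd, the gp130 kinase Jak2, the interferon-stimulated Ifit1 and Isg15, the glycolytic Pfkl, the adipocyte markers Lpl and Scd1, and Osmr. The OSM receptor subunit Osmr read 11.44 ± 2.17 in Stat3 WT and 8.35 ± 2.14 in Stat3 KO cells (SD, n = 2 each). Its difference was -3.07 within replicate 2 and -3.11 within replicate 3 (adjusted p = 1), and adjusted over the STAT3 target list alone it passed with the block (adjusted p = 0.00799). The other fixed genes also failed the test (adjusted p = 1 each). Their log2 differences were -2.07 for Socs3, -1.83 for Bcl3, -1.68 for Cebpd, 2.26 for Egr1, 1.05 for Fos, -1.16 for Il6, -0.91 for Lifr, 0.52 for Il6st, 0.07 for Junb and -0.05 for Myc, and with values under 5 set to 5 that of Il6 was -0.76. Leaving out 1 array gave ranges of 0.04 to 4.48 for Egr1, -3.53 to -0.6 for Socs3, -3.03 to -0.63 for Bcl3, -2.59 to -0.77 for Cebpd, -4.62 to -1.55 for Osmr and 0.13 to 0.91 for Il6st, and the direction of Fos, Il6, Lifr, Junb and Myc turned. Over all probe sets limma called 0, and 151 had an unadjusted p under 0.05. Fitted with the replicate block, limma called 0, and 653 had an unadjusted p under 0.05. At least 2-fold separation between all arrays held for 49 probe sets. Any separation held for 19.2%, against 33.3% by chance if arrays were interchangeable. A difference between replicate numbers makes groups overlap, so a share under 33.3% does not mean fewer separations than chance.

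**Figure D1:**
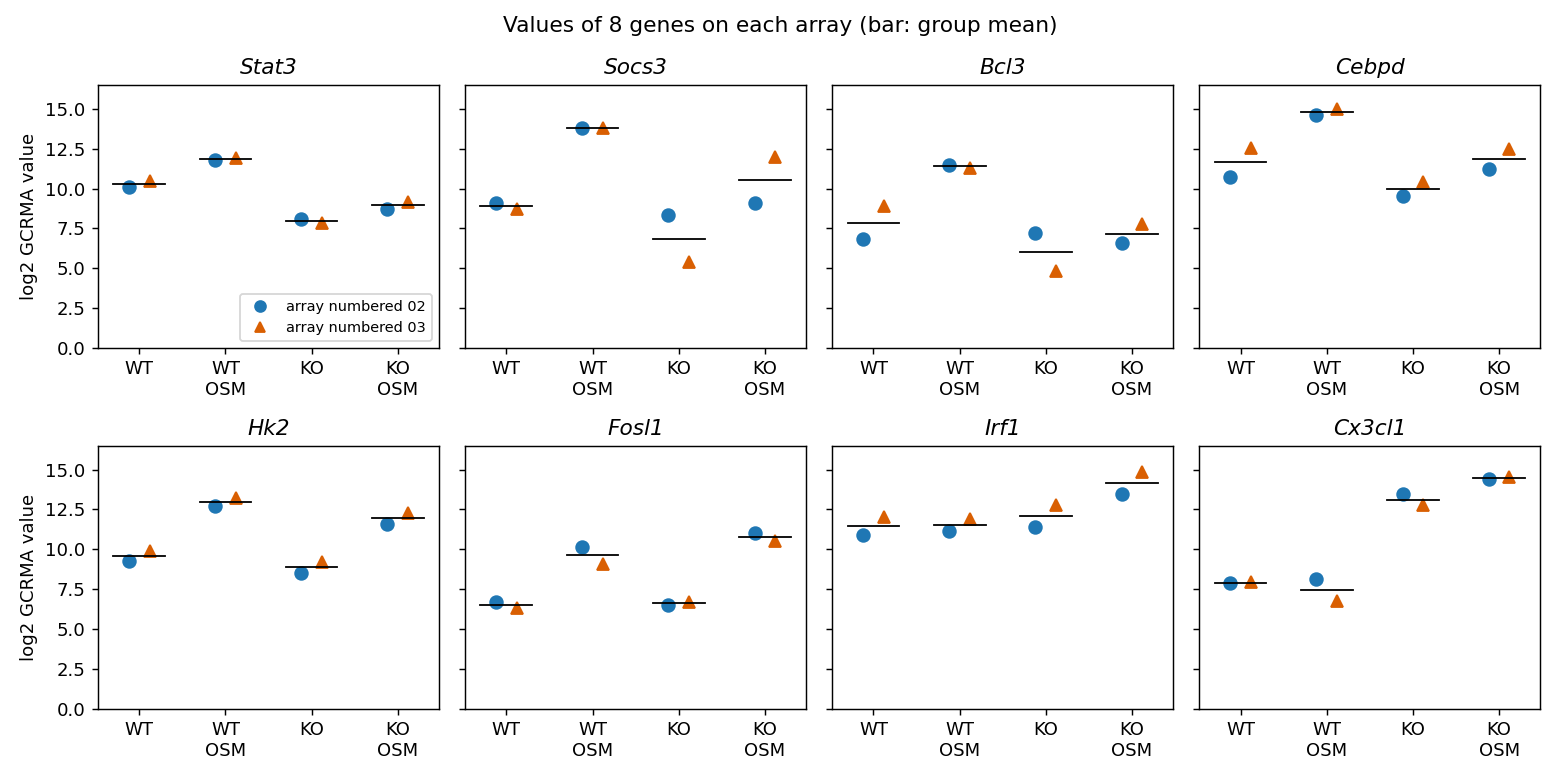
Log2 GCRMA value (vertical axis) of 8 genes on each of the 8 arrays, with circles for replicate 2 (numbered 02), triangles for replicate 3 (numbered 03) and bars for group means. Socs3 read 13.80 on both Stat3 WT arrays with OSM, and 9.12 and 11.98 on the Stat3 KO arrays with OSM.

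The second comparison asked what 30 minutes of OSM did in cells with Stat3. Hk2, which catalyses the first step of glycolysis, read 12.97 ± 0.37 with OSM and 9.58 ± 0.47 without (SD, n = 2 each), a log2 difference of 3.39 ± 0.44 (SE). The epidermal growth factor family ligand Ereg differed by 4.15 ± 0.57, the AP-1 subunit Fosl1 by 3.10 ± 0.46, the transcription factor Snai1 by 2.22 ± 0.30 and the interleukin-17 receptor subunit Il17ra by 2.20 ± 0.35 (SE). These 5 genes had the smallest p-values without passing, with limma adjusted p-values of 0.523 for Hk2, Snai1 and Ereg, 0.64 for Fosl1 and 0.791 for Il17ra. With the replicate block Hk2 passed (adjusted p = 0.019), though not when Stat3 KO OSM replicate 3, an array outside this comparison, was left out as well. Socs3, the feedback inhibitor of gp130 signalling, read 13.80 on both arrays with OSM and 8.91 ± 0.27 (SD, n = 2) without (adjusted p = 1).

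The STAT3 target list rose with OSM in Stat3 WT cells, with a median log2 difference of 1.16 and 27 of 32 members above 0 (camera adjusted p = 7.12e-16, and adjusted p = 0.276 with an estimated correlation). Adjusted over the list alone, 5 members passed, namely Socs3 (4.89), the transcription factor Cebpd (3.12), the protease inhibitor Timp1 (1.71), Stat3 (1.57) and the angiogenic factor Vegfa (1.41). With the replicate block 13 passed in this way, Bcl3, Junb and Osmr among them. The hypoxia and glycolysis genes rose, with a median of 0.64 and 22 of 25 above 0 (camera adjusted p = 3.07e-12, and adjusted p = 0.0248 with an estimated correlation). This was the only list call of the 34 in the 5 comparisons that held with an estimated correlation, and with the replicate block that p became 0.162. Hk2 passed when adjusted over the list alone. The MAPK feedback genes rose, with a median of 0.98 and 11 of 12 above 0 (camera adjusted p = 7.98e-10, and adjusted p = 0.234 with an estimated correlation). Ereg and Fosl1 passed when adjusted over the list alone. The immediate early genes rose, with a median of 0.67 and 22 of 31 above 0 (camera adjusted p = 8.62e-07, and adjusted p = 0.429 with an estimated correlation). Medians within replicates 2 and 3 were 0.38 and 0.60 for the hypoxia and glycolysis genes, 1.55 and 0.63 for the MAPK feedback genes and 0.86 and 0.49 for the immediate early genes.

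The NF-kB and chemokine genes rose, with a median of 0.67 and 18 of 21 above 0 (camera adjusted p = 6.83e-06, and adjusted p = 0.379 with an estimated correlation), but not without Stat3 WT untreated replicate 2 (adjusted p = 0.181). The gp130 pathway components had a median of 0.35 (camera adjusted p = 0.00224, and adjusted p = 0.469 with an estimated correlation), and the call was lost without Stat3 WT untreated replicate 2 (adjusted p = 0.351) or Stat3 WT OSM replicate 3 (adjusted p = 0.179). Within replicate 2 the gp130 median was 0.31 with 18 of 25 above 0, and within replicate 3 it was -0.01 with 12 above 0. The NF-kB medians were 0.74 and 0.31 within these replicates, and the HOX medians -0.27 and -0.14. The interferon-stimulated genes had a median of 0.79 with 25 of 31 above 0 (camera adjusted p = 0.00224, and adjusted p = 0.774 with an estimated correlation), and leaving out Stat3 WT untreated replicate 2 or Stat3 WT OSM replicate 3 gave adjusted p = 0.919 and 0.936. Proteases with a median of 0.22 and HOX genes with a median of -0.19 passed narrowly (camera adjusted p = 0.0499 for both, and adjusted p = 0.484 and 0.594 with an estimated correlation). The protease call was lost without Stat3 WT untreated replicate 2 (adjusted p = 0.706) and turned without Stat3 WT OSM replicate 3 (adjusted p = 0.984). The HOX call was lost without Stat3 WT untreated replicate 3 (adjusted p = 0.859) or Stat3 WT OSM replicate 2 (adjusted p = 0.675). Both calls also ended after quantile normalization (adjusted p = 0.0807 and 0.0839) and with values under 5 set to 5 (adjusted p = 0.102 and 0.0622), and the protease call without the filter (adjusted p = 0.0561) and with the most variable probe set (adjusted p = 0.0808). The other 11 lists did not pass. Among the fibroblast programmes the proliferation genes had a median of -0.31 (camera adjusted p = 0.219), the p53 and CDK inhibitor genes -0.14 (adjusted p = 0.356), the matrix genes -0.11 (adjusted p = 0.318), the contractile genes 0.04 (adjusted p = 0.126), the antioxidant genes 0.07 (adjusted p = 0.271), and the oxidative phosphorylation genes -0.04 (adjusted p = 0.499). The cholesterol synthesis genes, heat shock genes and muscle markers had medians of 0.07, -0.02 and -0.07 (adjusted p = 0.972 each), and the endothelial markers 0.09 (adjusted p = 0.499). The adipocyte markers had a median of -0.36 (adjusted p = 0.122) and passed with the replicate block (adjusted p = 0.0302, and adjusted p = 0.284 with an estimated correlation).

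The remaining fixed genes failed the test over all probe sets in Stat3 WT cells (adjusted p = 1 each). Their log2 differences with OSM were 3.54 for Bcl3, 1.98 for Junb, 2.74 for Egr1, 2.07 for Osmr, 1.15 for Myc, 0.94 for Il6st, 0.21 for Lifr and 0.10 for Fos. They ranged, with 1 array left out, from 2.51 to 4.57 for Bcl3, 1.38 to 2.59 for Junb, 0.52 to 4.96 for Egr1, 0.54 to 3.61 for Osmr, 0.17 to 2.13 for Myc and 0.59 to 1.28 for Il6st, and Lifr, Fos and Il6 turned. Il6 differed by 0.19 within replicate 2 and 3.71 within replicate 3. Over all probe sets limma called 0, and 126 had an unadjusted p under 0.05. In the fit with the replicate block 1 probe set was called, and 485 had an unadjusted p under 0.05. At least 2-fold separation between all arrays held for 70 probe sets, 53 of them higher with OSM. Any separation held for 17.6%, against 33.3% by chance.

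The third comparison asked the same of cells without Stat3. Ereg read 10.85 ± 0.13 with OSM and 4.0 ± 0.91 without (SD, n = 2 each), a log2 difference of 6.85 ± 0.57 (SE). The membrane-anchored semaphorin Sema7a differed by 6.20 ± 0.70, Fosl1 by 4.14 ± 0.46, Hk2 by 3.08 ± 0.44 and the prostaglandin E2 receptor Ptger4 by 2.88 ± 0.48 (SE). None of these 5 genes with the smallest p-values passed, the limma adjusted p-values being 0.116 for Ereg, 0.236 for Sema7a and Fosl1, 0.513 for Hk2 and 1 for Ptger4. Sema7a was under 5 without OSM, and with values under 5 set to 5 its difference was 3.48. With the replicate block Ereg and Hk2 passed (adjusted p = 0.0214 each). Socs1, an inhibitor of JAK kinases, read 1.14 and 4.10 without OSM and 8.31 and 11.40 with it (adjusted p = 1).

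The MAPK feedback genes rose with OSM in Stat3 KO cells, with a median of 1.97 and 10 of 12 above 0 (camera adjusted p = 9.72e-12, and adjusted p = 0.32 with an estimated correlation). Ereg, Fosl1 and Errfi1 (4.37 ± 1.05, SE), an inhibitor of epidermal growth factor receptors, passed when adjusted over the list alone. The immediate early genes rose, with a median of 1.09 and 26 of 31 above 0 (camera adjusted p = 7.37e-09, and adjusted p = 0.506 with an estimated correlation). The STAT3 target list rose in these cells too, with a median of 0.77 and 30 of 32 above 0 (camera adjusted p = 1.64e-07, and adjusted p = 0.557 with an estimated correlation). Socs1 (7.23) was its only member to pass adjusted over the list alone. With the replicate block 8 passed in this way, Osmr, Fos, Cebpd and Stat3 among them. The interferon-stimulated genes rose, with a median of 1.67 and 29 of 31 above 0 (camera adjusted p = 3.39e-05, and adjusted p = 0.717 with an estimated correlation). Their median was 1.73 within replicate 2 and 1.28 within replicate 3. The pooled direction turned without Stat3 KO untreated replicate 2 or Stat3 KO OSM replicate 3, in fits unbalanced in replicate number. With the replicate block the upward call held without Stat3 KO OSM replicate 3. Adjusted over the list alone 0 interferon-stimulated genes passed, and 9 did with the replicate block. That block also raised the MAPK feedback genes from 3 to 8, Myc among them, and the immediate early genes from 1 to 6, Fos among them.

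The NF-kB and chemokine genes had a median of 0.88 (camera adjusted p = 0.00422, and adjusted p = 0.557 with an estimated correlation). Their call was lost without Stat3 KO OSM replicate 3, but held without that array when the replicate block was used. The gp130 pathway components had a median of 0.23 (camera adjusted p = 0.00634, and adjusted p = 0.557 with an estimated correlation), and the same array ended that call (adjusted p = 0.318). The heat shock genes had a median of 0.53 with 10 of 13 above 0 (camera adjusted p = 0.00953, and adjusted p = 0.6 with an estimated correlation), but not without Stat3 KO untreated replicate 2 (adjusted p = 0.535). The contractile genes had a median of 0.20 with 12 of 12 above 0 (camera adjusted p = 0.0122, and adjusted p = 0.557 with an estimated correlation), but not without Stat3 KO untreated replicate 2 (adjusted p = 0.219) or Stat3 KO OSM replicate 2 (adjusted p = 0.052). The fibroblast matrix genes fell, with a median of -0.25 (camera adjusted p = 0.0138, and adjusted p = 0.638 with an estimated correlation). That call was lost without Stat3 KO untreated replicate 2, Stat3 KO untreated replicate 3 or Stat3 KO OSM replicate 2 (adjusted p = 0.074, 0.0799 and 0.376). It was also lost with the most variable probe set (adjusted p = 0.0595) and after quantile normalization (adjusted p = 0.0652), the gp130 call without the filter (adjusted p = 0.124) and the heat shock call with the most variable probe set (adjusted p = 0.0589). Within replicates 2 and 3 the heat shock medians were 0.58 and 0.15, the contractile medians 0.54 and 0.09, and the matrix medians -0.33 and -0.13. The block without Stat3 KO OSM replicate 3 ended the gp130, matrix and contractile calls (adjusted p = 0.137, 0.164 and 0.287).

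The oxidative phosphorylation genes in Stat3 KO cells had a median of -0.14 (camera adjusted p = 0.0436, and adjusted p = 0.781 with an estimated correlation). Their call was lost without Stat3 KO untreated replicate 2 (adjusted p = 0.932) and turned without Stat3 KO OSM replicate 3 (adjusted p = 0.46), and it ended with values under 5 set to 5 (adjusted p = 0.0505) and with the block without that array (adjusted p = 0.187). Within replicate 2 their median was -0.01 with 20 of 41 above 0, and within replicate 3 it was -0.19 with 5 above 0. The hypoxia and glycolysis genes had a median of 0.07, and 0.24 and 0.03 within replicates 2 and 3 (camera adjusted p = 0.0436, and adjusted p = 0.506 with an estimated correlation). They did not pass with the replicate block (adjusted p = 0.136), without Stat3 KO untreated replicate 3 (adjusted p = 0.335) or without Stat3 KO OSM replicate 2 (adjusted p = 0.421). Nor did they without the filter, with the most variable probe set, with values under 5 set to 5 or with the block without Stat3 KO OSM replicate 3 (adjusted p = 0.168, 0.0547, 0.053 and 0.134). The other 9 lists had camera adjusted p-values from 0.0725 to 0.949. The fixed genes failed the test over all probe sets (adjusted p = 1 each). Their log2 differences were 3.71 for Socs3, 3.39 for Osmr, 2.99 for Fos, 2.20 for Egr1, 1.88 for Cebpd, 1.84 for Il6, 1.49 for Lifr, 1.28 for Myc, 1.14 for Bcl3, 1.09 for Junb, 0.99 for Stat3 and 0.10 for Il6st. When 1 array was left out the ranges were 2.24 to 5.17 for Socs3, 1.88 to 4.91 for Osmr, 1.19 to 3.22 for Egr1, 1.27 to 2.49 for Cebpd, 0.52 to 3.16 for Il6, 0.08 to 2.9 for Lifr, 0.93 to 1.64 for Myc, 0.43 to 1.75 for Junb and 0.76 to 1.23 for Stat3, and Fos, Bcl3 and Il6st turned. With values under 5 set to 5 the difference was 1.84 for Fos and 1.03 for Il6. Over all probe sets limma called 0, and 138 had an unadjusted p under 0.05. When blocked by replicate, limma called 2, and 746 had an unadjusted p under 0.05. At least 2-fold separation between all arrays held for 51 probe sets, 47 of them higher with OSM. Any separation held for 26.7%, against 33.3% by chance.

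**Figure D2:**
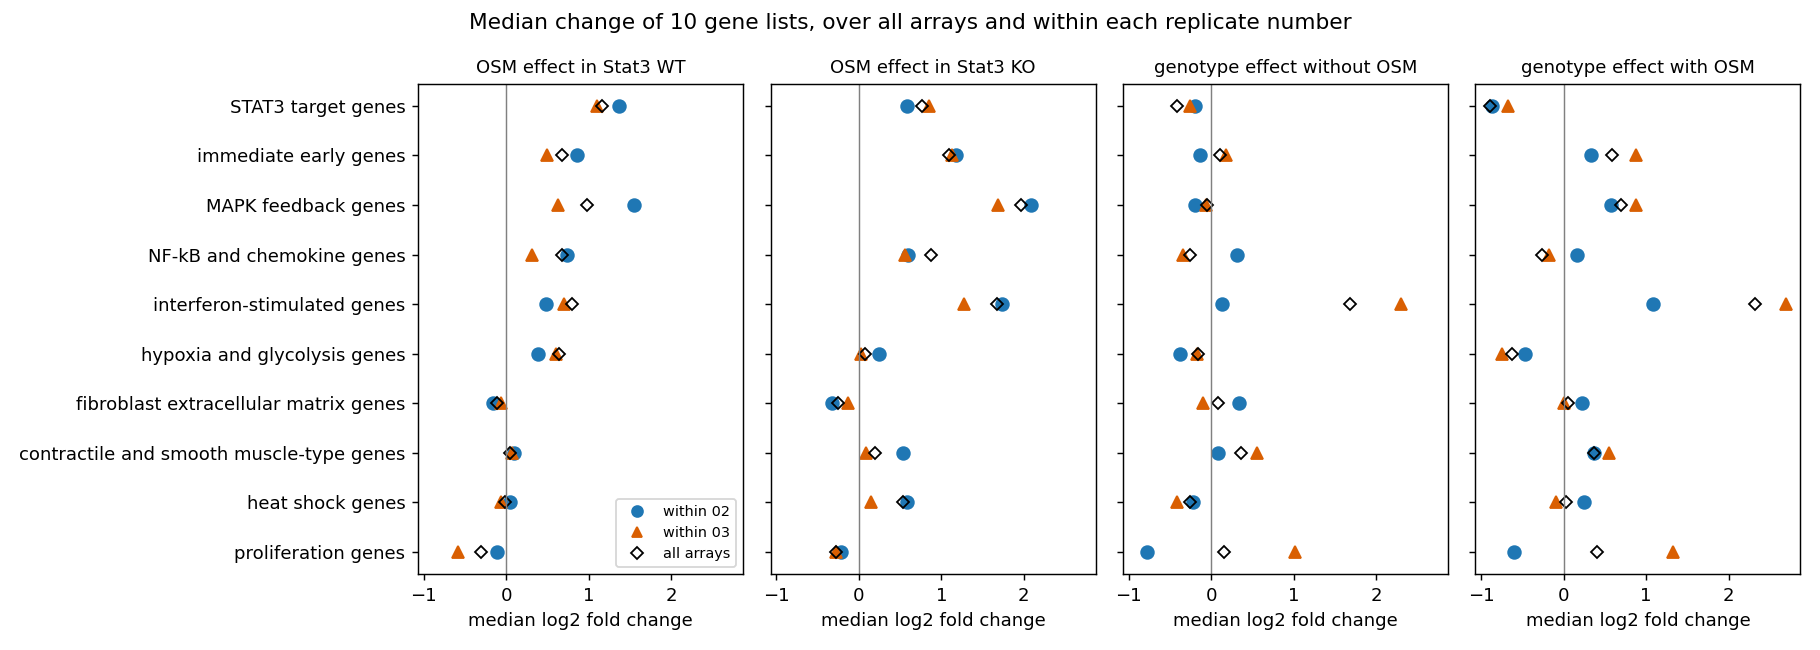
Median log2 fold change (horizontal axis) of 10 gene lists in 4 comparisons, as diamonds over all arrays, circles within replicate 2 and triangles within replicate 3. The STAT3 target list lies at 1.36 and 1.10 within the replicates for OSM in Stat3 WT cells, and the interferon-stimulated genes lie at 0.13 and 2.30 for genotype without OSM.

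The difference between both OSM responses was tested as an interaction, Stat3 KO minus Stat3 WT. Sema7a read 2.35 ± 0.36 without OSM and 2.25 ± 0.40 with it in Stat3 WT cells, and 2.28 ± 0.22 and 8.48 ± 1.41 in Stat3 KO cells (SD, n = 2 each), an interaction of 6.29 ± 0.99 (SE), or 3.48 with values under 5 set to 5, since all but the last of these means lie under 5. The interaction was 3.08 ± 0.68 for Ptger4, -2.66 ± 0.69 for the co-stimulatory ligand Tnfsf9, -4.0 ± 1.15 for the glycosyltransferase Gcnt2 and 1.26 ± 0.38 for the sterol synthesis enzyme Hmgcs1 (SE), and with values under 5 set to 5 that of Tnfsf9 was -1.22. None of these 5 genes with the smallest p-values passed (limma adjusted p = 1 each). The hypoxia and glycolysis genes responded less in Stat3 KO cells, with a median of -0.29 and 2 of 25 members above 0 (camera adjusted p = 0.000484, and adjusted p = 0.186 with an estimated correlation). Within replicate 2 their median was -0.07 with 9 above 0, and within replicate 3 it was -0.59 with 4 above 0. The call was lost with the block without Stat3 KO OSM replicate 3 (adjusted p = 0.0785). The MAPK feedback genes responded more, with a median of 0.77 and 11 of 12 above 0 (camera adjusted p = 0.0118, and adjusted p = 0.838 with an estimated correlation). This call was lost without Stat3 WT untreated replicate 3, Stat3 WT OSM replicate 3, Stat3 KO untreated replicate 2 or Stat3 KO OSM replicate 3 (adjusted p = 0.385, 0.0588, 0.361 and 0.0968), or with the block without Stat3 KO OSM replicate 3 (adjusted p = 0.116). The MAPK feedback medians within replicates 2 and 3 were 0.90 and 0.51.

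The heat shock genes had an interaction median of 0.35 with 13 of 13 above 0 (camera adjusted p = 0.0143, and adjusted p = 0.877 with an estimated correlation), but not without Stat3 WT untreated replicate 3, Stat3 WT OSM replicate 2 or Stat3 KO untreated replicate 2 (adjusted p = 0.553, 0.184 and 0.446), or with the most variable probe set (adjusted p = 0.0789). The STAT3 target list had a median of -0.65 with 11 of 32 above 0 (camera adjusted p = 0.0436, and adjusted p = 0.877 with an estimated correlation). It did not pass with the replicate block (adjusted p = 0.155), with that block without Stat3 KO OSM replicate 3 (adjusted p = 0.168) or with the most variable probe set (adjusted p = 0.138), nor without Stat3 WT untreated replicate 2, Stat3 WT OSM replicate 3 or Stat3 KO untreated replicate 3 (adjusted p = 0.959, 0.531 and 0.557), and it turned without Stat3 KO OSM replicate 2 (adjusted p = 0.863). The other 16 lists had camera adjusted p-values from 0.0551 to 0.988, and with the block the interferon-stimulated genes and the proteases passed as well (adjusted p = 0.0416 each, and adjusted p = 0.816 and 0.713 with an estimated correlation). The interferon-stimulated interaction median was 0.60 with 23 of 31 above 0 within replicate 2, and 0.02 with 16 above 0 within replicate 3. The protease medians were -0.18 and -0.33, and the STAT3 target medians -0.52 and -0.12. No member of any list passed the interaction test adjusted over the list alone, and with the block Irf1 and Socs1 did. The fixed genes had interactions of -1.19 for Socs3, -2.40 for Bcl3, -1.24 for Cebpd, -0.90 for Junb, 2.89 for Fos, -0.54 for Egr1, 0.14 for Myc, 1.32 for Osmr, -0.84 for Il6st, 1.28 for Lifr, -0.58 for Stat3 and -0.11 for Il6 (adjusted p = 1 each). Bcl3 ranged from -3.6 to -1.2, Cebpd from -2.15 to -0.33, Junb from -1.55 to -0.24, Il6st from -1.23 to -0.45 and Stat3 from -0.82 to -0.35 with 1 array left out, and the other 7 turned.

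Over all probe sets limma called 0 for the interaction, and 29 had an unadjusted p under 0.05. Blocked by replicate number, limma called 0, and 248 had an unadjusted p under 0.05. In 86 probe sets the replicate-wise OSM differences were at least 2-fold apart between the genotypes, and in 45.6% they did not overlap, against 33.3% by chance. Across 5195 genes, which are not independent replicates, the log2 differences with OSM in the 2 genotypes had a Pearson r of 0.47 and a Spearman rho of 0.296. Within replicate 2 the r was 0.316 and within replicate 3 it was 0.493, against 0.586 between the replicates of Stat3 WT and 0.523 between those of Stat3 KO. Pearson r was 0.058 without Stat3 WT untreated replicate 2 and 0.087 without Stat3 WT OSM replicate 3. Leaving out 1 array unbalances the replicate numbers, so part of their difference enters 1 OSM effect by construction. These values therefore do not show how alike the responses are.

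The last comparison set the OSM-treated lines against each other. Cx3cl1 was higher in Stat3 KO cells, at 14.47 ± 0.10 against 7.46 ± 0.96 in Stat3 WT cells (SD, n = 2 each), a log2 difference of 7.01 ± 0.50 (SE, limma adjusted p = 0.0488), and it was the only probe set of the 6756 to pass. The Cx3cl1 call was lost without Stat3 WT OSM replicate 3, Stat3 KO OSM replicate 2 or Stat3 KO OSM replicate 3 (adjusted p = 0.119, 0.468 and 0.325), while its log2 difference was then 6.33, 7.09 and 6.94. It was also lost without the intensity trend, with robust estimation, after quantile normalization, after median centring, with values under 5 set to 5 or with only both groups compared (adjusted p = 0.0581, 0.0587, 0.083, 0.065, 0.0532 and 0.84). With the replicate block limma called 7 probe sets, 4 higher and 3 lower in Stat3 KO cells. Besides Cx3cl1 (adjusted p = 0.0162) these were the interferon-responsive transcription factor Irf1 (2.64, adjusted p = 0.0387), Postn (3.61, adjusted p = 0.0387), the adhesion molecule Selp (-5.81, adjusted p = 0.0162), the motor protein Myo5b (-3.82, adjusted p = 0.0476), Stat3 (-2.94, adjusted p = 0.0476) and a second probe set of the receptor Notch1 (4.75, adjusted p = 0.0476). The Notch1 probe set with the highest mean gave 1.04 and did not pass with the block (adjusted p = 0.233). Irf1, Selp, Myo5b and Notch1 were named after their values were seen. Fewer probe sets were called with the block when Stat3 KO OSM replicate 3 was left out.

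The interferon-stimulated genes were higher in OSM-treated Stat3 KO cells, with a median of 2.32 and 30 of 31 above 0 (camera adjusted p = 2.59e-08, and adjusted p = 0.847 with an estimated correlation). The median was 1.08 within replicate 2 and 2.69 within replicate 3. The call was lost without Stat3 KO OSM replicate 3, but held without that array when the replicate block was used. Of these genes 0 passed adjusted over the list alone, and with the replicate block 11 did, all higher. The hypoxia and glycolysis genes were lower, with a median of -0.63 and 3 of 25 above 0 (camera adjusted p = 2.86e-07, and adjusted p = 0.0694 with an estimated correlation). The STAT3 target list was lower, with a median of -0.89 and 9 of 32 above 0 (camera adjusted p = 0.000344, and adjusted p = 0.847 with an estimated correlation), but not without Stat3 KO OSM replicate 2 (adjusted p = 0.311). Adjusted over the list alone 4 of its members passed, Bcl3 (-4.23), Cebpd (-2.92) and Stat3 being lower and Socs1 (7.36, or 4.85 with values under 5 set to 5) higher. With the replicate block 12 passed, 9 of them lower, including Osmr (adjusted p = 0.0261) and Stat3. Since Stat3 is the gene missing from the Stat3 KO line, its passing says nothing about its targets. The contractile genes were higher, with a median of 0.37 (camera adjusted p = 0.000344, and adjusted p = 0.605 with an estimated correlation), but not without Stat3 WT OSM replicate 3 (adjusted p = 0.0703) or with the block without Stat3 KO OSM replicate 3 (adjusted p = 0.111).

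The MAPK feedback genes were higher in OSM-treated Stat3 KO cells, with a median of 0.70 (camera adjusted p = 0.00322, and adjusted p = 0.847 with an estimated correlation), but not without Stat3 KO OSM replicate 3, whether without a block (adjusted p = 0.119) or with it (adjusted p = 0.0806). The immediate early genes had a median of 0.58 (camera adjusted p = 0.0212, and adjusted p = 0.972 with an estimated correlation), lost without Stat3 WT OSM replicate 2 (adjusted p = 0.163) and turned without Stat3 KO OSM replicate 3 (adjusted p = 0.992). They also failed without the filter (adjusted p = 0.565) and with the block without Stat3 KO OSM replicate 3 (adjusted p = 0.389). Members of called lists that passed adjusted over the list alone with the block were the hypoxia genes Hk2, P4ha2 and Pfkl, all lower, and the contractile genes Acta2, Itga5 and Vcl, the immediate early genes Egr2 and Fos, and the MAPK feedback genes Ereg and Hbegf, all higher. The other 14 lists had camera adjusted p-values from 0.0517 to 0.94, and with the block the HOX genes passed as well, at a median of 0.40 (adjusted p = 0.0255, and adjusted p = 0.582 with an estimated correlation). Medians within replicates 2 and 3 were 0.73 and 0.27 for the HOX genes, 0.33 and 0.88 for the immediate early genes, 0.57 and 0.88 for the MAPK feedback genes, and -0.47 and -0.75 for the hypoxia and glycolysis genes. The proliferation genes, which did not pass, again went in opposite directions within the numbers. Their median was -0.6 with 4 of 32 above 0 within replicate 2, and 1.32 with 31 above 0 within replicate 3. For each of the 34 list calls the median, the mean and the camera test had the same sign, while for some lists that did not pass they differed. Tnc (2.38) passed when adjusted over the matrix list alone. The other fixed genes differed by -3.25 for Socs3, -1.77 for Osmr, 3.94 for Fos, 1.72 for Egr1, -0.82 for Junb, -1.27 for Il6, 0.38 for Lifr, -0.32 for Il6st and 0.09 for Myc (adjusted p = 1 each). Without 1 array the differences ranged from 0.25 to 7.63 for Fos, -4.68 to -1.82 for Socs3, -2.97 to -0.56 for Osmr, 1.13 to 2.32 for Egr1 and -1.48 to -0.16 for Junb, and those of Il6, Lifr, Il6st and Myc turned. An unadjusted p under 0.05 was found for 243 probe sets, and for 814 with the replicate block. At least 2-fold separation between all arrays held for 131 probe sets. Any separation held for 24.9%, against 33.3% by chance.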

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

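Of the tests below, 4 were chosen only after the result was seen, namely both tests on the interferon-stimulated genes, the test of a Stat3 signal shared by replicate 3 arrays, and the test on the spiked controls, as was the setting of values under 5 to 5. Results whose OSM effect differed between the genotypes are given first. In the interaction the STAT3 target genes (camera adjusted p = 0.0436), the MAPK feedback genes (adjusted p = 0.0118), the hypoxia and glycolysis genes (adjusted p = 0.000484) and the heat shock genes (adjusted p = 0.0143) passed. With an estimated correlation none of these lists passed (adjusted p = 0.877, 0.838, 0.186 and 0.877). With the replicate block the STAT3 target list did not pass (camera adjusted p = 0.155). That block without Stat3 KO OSM replicate 3 also ended the MAPK feedback and the hypoxia and glycolysis calls. For Hmgcs1 both Stat3 WT differences with OSM lay below 0 (-0.46 and -0.69) and both Stat3 KO differences above 0 (1.10 and 0.28), and its interaction of 1.26 did not pass the test. For Sema7a the differences were -0.12 and -0.07 in Stat3 WT cells and 7.35 and 5.05 in Stat3 KO cells, and its interaction of 6.29 did not pass either. Without OSM and in Stat3 WT cells Sema7a read under 5, near background, so the sign of its Stat3 WT differences carries no information, and with values under 5 set to 5 its interaction was 3.48. No group held enough arrays for a test of single outlying arrays.

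The interferon-stimulated genes were higher in Stat3 KO than in Stat3 WT cells with OSM (camera adjusted p = 2.59e-08, and adjusted p = 0.847 with an estimated correlation) and without it (camera adjusted p = 4.64e-06, and adjusted p = 0.913 with an estimated correlation). A difference between the replicate numbers shared equally by all groups is argued against by the design alone, because each number holds all 4 groups, so it cancels. With OSM and the number as a block 11 of the 31 members passed adjusted over the list alone, all higher in Stat3 KO cells. Their passing adds nothing against such a difference. The fry test with that block gave adjusted p = 0.0152 for either direction and 0.252 for 1 direction. The difference between numbers was, however, unequal between the genotypes. Across probe sets it correlated at 0.9106 within Stat3 WT and 0.7935 within Stat3 KO, and at 0.589 to 0.6638 between the genotypes. For the interferon-stimulated genes the genotype medians within replicates 2 and 3 were 0.13 and 2.30 without OSM. With OSM they were 1.08 and 2.69. Whether the lines or single arrays bring about this inequality stays open. On the first principal component Stat3 KO OSM replicate 2 lay at -19.43, nearer replicate 3 than the other replicate 2 arrays at -54.69 to -48.05. Without Stat3 KO untreated replicate 3 the median difference before OSM was -0.55, but leaving it out unbalances the numbers and by itself shifts the median by an estimated -0.86, so whether 1 array stands apart stays open. Whether the genotype or the history of each line accounts for the difference stays open and was not tested, because 1 line stands for each genotype.

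The second Stat3 probe set, which was bright in Stat3 WT and dim in untreated Stat3 KO cells, read 7.30 in Stat3 KO OSM replicate 3 and 2.76 to 2.94 on the other Stat3 KO arrays. A signal shared by all arrays of replicate 3 is argued against by the pattern itself, because this probe set read 2.86 in Stat3 KO untreated replicate 3. That value is part of the pattern, so it is no further test. RNA of Stat3 WT cells in that sample cannot be told apart from other sources, because only 1 other transcript, Saa3, was bright enough in Stat3 WT and dim enough in Stat3 KO cells to serve as a marker. Saa3 lay below the level needed by 2.24 on the log2 scale (value -2.24), without a spread to judge it by. No biological explanation was tested.

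Between the replicate numbers 2465 probe sets differed when the arrays were split 4 against 4, and the highest count among the other splits was 5. Only 1 of the 35 splits, the real one, gave as many, the lowest share that 35 splits allow, which argues against chance without excluding it. The other splits were fitted without a term for number, so its difference entered their spread and lowered their counts. The gap between 2465 and 5 therefore overstates how far the real split stands out. Whole arrays also differed by number, with array medians of 5.27 to 5.39 in replicate 2 and 5.52 to 5.66 in replicate 3. These ranges lay close together, so renewed quantile normalization could move values little. After it the interferon-stimulated median was 3.28 and the proliferation median -2.27, against 3.41 and -2.19 before. For these lists this argues against the distribution of whole arrays as the only source. The 9 spiked bacterial and phage control probe sets, which are not cell RNA, were lower in replicate 3 by a median of 0.50 (value -0.5) and by 0.13 to 2.76, 7 without overlap and 2 with it, so hybridization or labelling stays open as a source of part of the difference. Separate cultures or times of the cells stay open and were not tested, and RNA quality stays open too, the 3' minus 5' actin difference being 0.33 to 0.53 in replicate 2 and 0.72 to 1.11 in replicate 3 while that of Gapdh overlapped (0.03 to 0.11 and 0 to 0.27).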

How the results depend on the processing

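Of the alternatives, setting values under 5 to 5, leaving out arrays in the list tests and the replicate block without Stat3 KO OSM replicate 3 were chosen after the data were seen. The count called was 0 under each alternative test for the genotype effect without OSM and for the interaction. With the replicate block 1 probe set was called for OSM in Stat3 WT, 2 for OSM in Stat3 KO and 7 for the genotype effect with OSM, against 0, 0 and 1. With the replicate block without Stat3 KO OSM replicate 3 these counts were 0, 1 and 2. With values under 5 set to 5 the last 2 were 1 and 0. The genotype effect with OSM had 0 calls with no intensity trend, robust estimation, only the groups compared, quantile normalization or median centring, and 0 to 1 with 1 array left out. The rule of 2-fold separation, which has no test, gave 49, 70, 51, 86 and 131 probe sets in the order of the comparisons. The correlation of the OSM effects was 0.058 to 0.512 with 1 array left out, which by construction adds part of the difference between numbers to 1 OSM effect. Over called genes the correlation could not be run, since none were called. The cause of the other changes was not tested.

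Of 34 list calls, 30 held without the filter, 32 with the replicate block, 26 with the most variable probe set per gene, 30 after quantile normalization, 29 with values under 5 set to 5, 23 with the replicate block without Stat3 KO OSM replicate 3, 1 with an estimated correlation, and by fry 2 in 1 direction and 5 in either direction. Another 33 list results passed only under alternatives, 22 of them only with 1 array left out and none with an estimated correlation. The other 11 were, for the genotype effect without OSM, heat shock genes (no filter 0.0235, block without that array 0.0285), for OSM in Stat3 WT, adipocyte markers (block 0.0302, without that array 0.0375), and for OSM in Stat3 KO, proliferation genes (block without that array 0.00239). In the interaction they were interferon-stimulated genes and proteases (block 0.0416 each), and NF-kB and HOX genes (no filter 0.0235 and 0.0443). For the genotype effect with OSM they were gp130, NF-kB and matrix genes (fry in either direction 0.0012, 0.0012 and 0.0243), and HOX genes (no filter 0.0139, block 0.0255). A further 33 list results passed in no setting, the lowest adjusted p being 0.0638. Of their 453 alternative values 93 had the other sign.

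Direction turned as follows, none of these values passing. Lifr (other probe sets) gave 0.66 and 0.38 without OSM and -0.11 and -0.01 for the interaction, Stat3 by its other probe set 0.40 for the interaction, Myc without OSM 0.05 quantile-normalized and 0.06 median-centred, and Fos for OSM in Stat3 WT -0.10 with values under 5 set to 5. Adjusted p-values of lists that turned were, for MAPK feedback genes without OSM, 0.983 (fry), 0.998 (replicate block) and 0.971 (block without Stat3 KO OSM replicate 3). Cholesterol genes gave 0.976 (fry) and 0.993 (quantile) for OSM in Stat3 WT, and 0.927 and 0.872 for OSM in Stat3 KO and the interaction (block without that array). Without the filter the interaction gave 0.791 for immediate early and for proliferation genes. The block without that array gave 0.116 for proliferation genes in the interaction and 0.549 with OSM. With OSM, NF-kB genes gave 0.451 (no filter), 0.942 (replicate block) and 0.91 (quantile), and oxidative phosphorylation genes 0.992 (fry), 0.794 (no filter) and 0.917 (replicate block). The cause was not tested.

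Leaving out 1 array leaves the groups unbalanced in replicate number, which by construction adds part of the difference between numbers to the comparison. The lowest and highest values follow for results that turned, some of which passed in opposite directions, such as the proliferation genes. Log2 differences for the genotype effect without OSM were -2.62 to 4.71 for Fos, -2.63 to 0.31 for Il6, -0.53 to 0.68 for Junb, -2.31 to 0.5 for Lifr and -1.03 to 0.93 for Myc. Log2 differences for OSM in Stat3 WT were -2.53 to 2.72 for Fos, -1.29 to 5.19 for Il6 and -0.73 to 1.14 for Lifr. Log2 differences for OSM in Stat3 KO were -0.06 to 2.33 for Bcl3, -0.7 to 6.68 for Fos and -0.29 to 0.49 for Il6st. Log2 differences for the interaction were -2.76 to 1.68 for Egr1, -0.79 to 6.58 for Fos, -3.35 to 3.12 for Il6, -0.12 to 2.69 for Lifr, -0.84 to 1.12 for Myc, -0.21 to 2.86 for Osmr and -2.65 to 0.28 for Socs3. Log2 differences for the genotype effect with OSM were -4.51 to 1.96 for Il6, -0.69 to 0.05 for Il6st, -0.24 to 0.99 for Lifr and -0.36 to 0.53 for Myc. List adjusted p-values for the genotype effect without OSM were 0.00259 to 0.693 for immediate early genes, 0.00343 to 0.924 for STAT3 target genes, 0.0424 to 0.292 for MAPK feedback genes, 1.27e-22 to 0.89 for interferon-stimulated genes, 0.00226 to 0.852 for NF-kB and chemokine genes, 3.9e-07 to 0.766 for proliferation genes, 0.0108 to 0.814 for oxidative phosphorylation genes and 0.000113 to 0.372 for cholesterol synthesis genes. List adjusted p-values for OSM in Stat3 WT were 0.0129 to 0.492 for matrix genes, 0.0193 to 0.859 for contractile genes, 0.00194 to 0.984 for proteases, 8.82e-12 to 0.000738 for proliferation genes, 0.00523 to 0.292 for oxidative phosphorylation genes, 0.00618 to 0.0611 for cholesterol synthesis genes and 0.0457 to 0.936 for antioxidant genes. List adjusted p-values for OSM in Stat3 KO were 1.88e-15 to 0.596 for interferon-stimulated genes, 0.0492 to 0.337 for proliferation genes and 2.72e-05 to 0.932 for oxidative phosphorylation genes. List adjusted p-values for the interaction were 0.00017 to 0.816 for immediate early genes, 1.75e-05 to 0.959 for STAT3 target genes, 3.66e-08 to 0.385 for interferon-stimulated genes, 0.0026 to 0.953 for NF-kB and chemokine genes, 0.00242 to 0.863 for matrix genes, 0.0337 to 0.992 for contractile genes, 1.06e-10 to 0.557 for proliferation genes, 0.000851 to 0.663 for oxidative phosphorylation genes and 5.02e-05 to 0.698 for cholesterol synthesis genes. List adjusted p-values for the genotype effect with OSM were 1.19e-05 to 0.992 for immediate early genes, 0.049 to 0.906 for gp130 components, 0.324 to 0.619 for NF-kB and chemokine genes, 0.00961 to 0.848 for matrix genes, 5.98e-12 to 0.887 for proliferation genes and 0.0114 to 0.126 for oxidative phosphorylation genes.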

Other observations

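The test on subsets of interferon-stimulated genes below was chosen only after the result was seen. Differences between the replicates reached further gene groups. In replicate 3 the STAT3 target genes were higher, with a median of 0.96 and 25 of 32 members above 0 (camera adjusted p = 0.0039, and adjusted p = 0.568 with an estimated correlation). The immediate early genes were higher, with a median of 0.96 and 24 of 31 above 0 (camera adjusted p = 0.00933, and adjusted p = 0.568 with an estimated correlation). The oxidative phosphorylation genes were lower, with a median of -0.46 and 8 of 41 above 0 (camera adjusted p = 0.000219, and adjusted p = 0.541 with an estimated correlation). Igtp, an interferon-inducible GTPase chosen after its values were seen, read 4.96 to 12.58 in replicate 2 and 10.12 to 14.97 in replicate 3.

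Epithelial, leukocyte, neural, and cartilage and bone markers and the sex-linked genes had too few measured members for a test. Among the leukocyte markers the receptor Csf1r read 8.80 to 10.20, Cd14 9.34 to 11.62 and Itgb2 4.80 to 6.46 over the 8 arrays. Among the neural markers Tubb3 read 10.83 to 12.44, Ncam1 11.59 to 12.32, Nefl 4.01 to 5.46 and Mbp 5.14 to 10.36. The epithelial markers were dim, with Krt8 at 2.50 to 5.66, Krt18 at 4.54 to 5.20 and Pkp1 at 4.51 to 5.57. Among the cartilage and bone markers the growth factor Bmp4 read 9.52 to 13.03, Bmp2 4.38 to 6.75 and Col11a1 4.40 to 5.69. Of the sex-linked genes the Y-linked Eif2s3y read 6.32 to 7.70 in Stat3 WT and 7.36 to 9.32 in Stat3 KO cells, Kdm5d 4.68 to 5.15, Kdm6a 7.95 to 10.89 and Eif2s3x 12.49 to 12.98.

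A hypothesis was that, among the interferon-stimulated genes, those known for interferon gamma and GAS sites may respond more to OSM in Stat3 KO cells than those known for type I interferon and ISRE sites. Within replicate 2 the medians were 2.91 over 11 genes and 0.34 over 14 genes, a difference of 2.57 ± 0.90 (SE). Within replicate 3 they were 1.75 and 1.37, a difference of 0.37 ± 0.41 (SE), so the test did not decide the question. These errors are over genes of single array pairs, which are correlated, so they understate the spread between arrays. In Stat3 WT cells the differences were 1.84 ± 0.58 and 2.00 ± 0.50 (SE).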
